A study of Mus musculus with 12 samples.

How the data were processed

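The series measured gene expression in primary cultures of cerebellar granule cells from lethargic mice, which carry a mutation in Cacnb4, the gene of the β4 subunit of voltage-gated calcium channels. Per the labels, the cells were taken from 129/SvJ mice at postnatal day 7, transduced with lentivirus for 12 hours right after plating, and lysed for RNA after 9 days in vitro. The virus carried 1 of 3 splice variants of β4 (β4a, β4b or β4e) or eGFP as the control, and an antimitotic drug was used against non-neuronal cells. RNA was extracted with Trizol, 500 ng per sample were amplified and labelled with biotin by a 3′ in vitro transcription kit, and each sample was hybridised to 1 Affymetrix mouse 3′ expression array. The 12 arrays formed 4 groups of 3, and the titles gave every group the same replicate numbers, 1 to 3.

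The deposited values were log2 intensities that the authors had made with GCRMA (background correction by probe sequence, normalization between arrays and 1 summary value per probe set); its version was not given in the sources used here. The values ran from 1.27 to 15.0 on the log2 scale, were not centred per probe set, and were used as deposited. The medians of the 12 arrays lay between 3.84 and 3.90. Of 45101 probe sets, 64 AFFX controls were left out of the tests. The annotation gave 1 gene symbol to 34945 probe sets, several to 932 and none to 9160, and 0 symbols needed an update through the gene identifier. A probe set was tested when its value was above 4 on the log2 scale in at least 3 of the 12 arrays, irrespective of group. This left 23044 probe sets, 19477 of them with 1 gene symbol. Differences from a mean below 4, such as those of Fosb, Rrm2b and Dpp10 from eGFP, are against values near background and are not exact.

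All 12 arrays were fitted in 1 linear model with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 1 coefficient per group, 8 residual degrees of freedom). The contrasts were each variant against eGFP, each pair of variants, and the mean of the 3 variants against eGFP, and a moderated F test asked for any difference among the 4 groups. P values were two-sided and adjusted by Benjamini-Hochberg over the 23044 probe sets of a contrast, with a threshold of 0.05. If no probe set differed, a share of about 0.05 of them would lie at an unadjusted p under 0.05. A count near or below that share does not by itself show a difference. The model, the filter, the threshold, the gene lists, the rule for naming genes and the alternatives were fixed before the data were examined, apart from the additions named here and in the closing section. A fit with the replicate number as a block (6 residual degrees of freedom) was one of these alternatives. Whether the numbers paired the arrays was checked on the deviations of each array from its group mean: all 18 pairs of arrays that shared a number correlated positively (r across probe sets, 0.699 to 0.884), and other pairs reached at most 0.146. The blocked counts of probe sets, and the blocked values of the genes that passed with the block, are therefore given beside those without it.

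Genes were named by rule. For each variant against eGFP these were up to 12 probe sets per direction with the largest log2 change among those past the threshold, annotated to exactly 1 gene and with no overlap between the arrays of the groups. Where fewer passed, up to 6 per direction with the smallest p were named as not passing. The 5 per direction with the smallest p were named for each pair of variants, and 10 for the F test. Cacnb4 was named in each comparison with eGFP, together with examples from the lists. Applying the rule to the blocked fit and to the mean of the variants was chosen after seeing the data. In the blocked fit, in place of no overlap, the differences within the 3 replicate numbers had to share 1 sign.

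A set of 30 gene lists was written from general knowledge: voltage-gated calcium channel subunits, reported β4 nuclear partners and targets, granule cell identity, granule progenitors and the Shh pathway, cell cycle, activity-regulated genes, glutamate receptors and postsynaptic density, GABA receptors, presynaptic vesicle machinery, potassium channels, sodium and HCN channels, calcium handling, interferon response, cytokines, unfolded protein response, heat shock, p53 and apoptosis, cholesterol synthesis, hypoxia and glycolysis, Wnt targets, axon cytoskeleton, ribosomal proteins, oxidative phosphorylation, and markers of astrocytes and Bergmann glia, oligodendrocytes, microglia, endothelium and pericytes, fibroblasts, Purkinje cells and interneurons. Lists were tested with camera (preset inter-gene correlation 0.01) on 1 probe set per gene, the one with the highest mean, over 10983 genes, and Benjamini-Hochberg adjusted over the lists of a contrast. Camera with an estimated correlation and fry were run beside it. A list needed 5 measured members, which left 29. The endothelial and pericyte list had 4 and was not tested. Members passing were also counted with p adjusted over the list alone.

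The alternatives were other filters, quantile normalization again, median centring, a trended and robust prior, array weights, the block, fits of the compared groups only, 1 probe set per gene, a threshold of 0.10, a test of each probe set alone (Welch), other list tests, and leaving out each array in turn. Further alternatives combined the block with some of these. Lists with 1 array left out were fitted without the block. Leaving out 1 array then spreads the replicate numbers unevenly over the groups, which can itself move a median or end a call. Other splits of the arrays were fitted in the same way.

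The pipeline was tested on simulated data with 23044 probe sets, of which 67 were changed by 0.5, 67 by 1 and 66 by 2 on the log2 scale. For β4a against eGFP without the block, 0%, 28.4% and 71.2% of these were recovered with 0 false calls, and with the block 31.3%, 83.6% and 95.5% with 12 false calls. For the mean of the variants the shares were 2.99%, 35.8% and 78.8% with 0 false calls, and with the block 43.3%, 85.1% and 100% with 15 false calls. The number of arrays limits the precision of every value. The p values measure only the spread between these samples: the labels do not say whether replicates were separate cultures or animals, so the spread may be technical.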

Results

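Expression was measured on 12 arrays of granule cell cultures from lethargic mice, 3 each with β4a, β4b, β4e or eGFP. Each value below is a log2 GCRMA intensity, given as mean ± SD over the arrays of a group. The design addresses which genes respond when 1 splice variant of the calcium channel β4 subunit is put back into neurons with a mutated Cacnb4, and whether the variants differ in this. The cultures carried strong granule cell transcripts: Gabra6, the GABA receptor subunit of mature granule cells, stood at 13.80 in the eGFP arrays. Correlations between arrays ran from 0.934 to 0.996. The 3′ minus 5′ difference of the Actb control probe sets lay between 0.82 and 1.09 and that of Gapdh between -0.05 and 0.40. In replicate 1 that of Gapdh was 0.39 with eGFP, 0.22 with β4a, 0.09 with β4b and 0.40 with β4e.

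Replicate number accounted for most of the variation between arrays. Of the total sum of squares, 76.0% lay between replicate numbers and 10.5% between groups. For 12 of 12 arrays the best-correlated other array shared the replicate number, and for 0 it shared the group. Because of this, differences within a replicate number are given for the genes that passed with the block for β4a or β4b against eGFP.

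**Figure D1:**
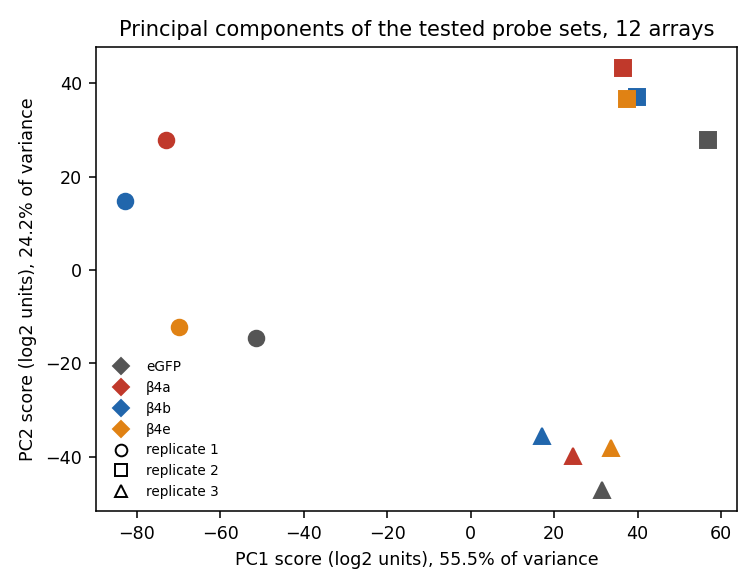
Principal components of the 12 arrays over the tested probe sets, with the group as colour and the replicate number as symbol. PC1 held 55.5% and PC2 24.2% of the variance, and arrays with the same replicate number lie together.

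The β4a cultures were compared with eGFP to find genes that follow this variant. Insm1, a zinc finger transcription factor of neuroendocrine cells and neuronal progenitors, stood at 7.71 ± 1.95 with β4a and 9.19 ± 1.64 with eGFP (n = 3 each). It was 2.79-fold lower, with differences of -1.08, -1.67 and -1.69 in replicates 1 to 3. Hook3, which links cargo to dynein, stood at 5.70 ± 0.38 against 4.63 ± 0.35. It was 2.09-fold higher, with differences of 1.10, 1.06 and 1.02. Rasgef1a, a guanine nucleotide exchange factor for Ras proteins, stood at 6.71 ± 1.09 against 5.69 ± 0.95, 2.03-fold higher (1.12, 1.19 and 0.75). With limma and Benjamini-Hochberg adjustment, 0 of 23044 probe sets passed without the block, with 363 at an unadjusted p under 0.05 (278 higher, 85 lower) and 0 by a test of each probe set alone. With the replicate block these 3 genes passed, among 3535 at an unadjusted p under 0.05. The adjusted p from limma was 0.0175 for Insm1, 0.0350 for Hook3 and 0.0488 for Rasgef1a, against 0.9999 for each without the block.

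These blocked calls depended on which arrays were included. When each of the 12 arrays was left out in turn, the log2 change of Insm1 in the blocked fit stayed between -1.66 and -1.39. Its limma adjusted p ran from 0.00121 to 0.254 and passed in 3 of 12 fits, those without eGFP replicate 1, β4e replicate 1 and β4e replicate 3. Hook3 ran from 0.99 to 1.11 (adjusted p 0.0325 to 0.349) and passed in 2 of 12, those without β4e replicate 1 or 3. Rasgef1a ran from 0.94 to 1.12 (0.0796 to 0.381) and passed in 0 of 12. Without the block these changes moved more on leaving out 1 array: Insm1 from -2.51 to -0.57, Rasgef1a from 0.39 to 1.56 and Hook3 from 0.86 to 1.28. A second probe set of Insm1 differed by -0.98 and a second one of Rasgef1a by 0.88. The 3 other probe sets of Hook3 differed by 0.07, 0.11 and 0.28.

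Other genes with the smallest p for β4a did not pass (limma adjusted p = 0.9999 for each without the block). Among these, Haghl stood at 8.18 ± 0.10 against 7.47 ± 0.18, Ahcyl1, which modulates the inositol trisphosphate receptor, at 10.34 ± 0.06 against 9.73 ± 0.06, and the chromatin remodeller Atrx at 9.88 ± 0.09 against 9.21 ± 0.09. Larp4, 2610507B11Rik and Srsf3 differed by 0.69, 0.60 and 0.58. Kcna2, a delayed rectifier potassium channel, stood at 10.23 ± 0.13 against 10.87 ± 0.14, and Zfyve28 at 10.10 ± 0.01 against 10.58 ± 0.15. Map3k10, Clock, Sod1 and Abl2 differed by -0.59, -0.50, -0.45 and -0.36. By the blocked p, the further genes were A830010M20Rik (1.23), Clybl (0.76), the axon guidance receptor Robo1 (0.73), Mtrex (-0.84), Pdlim7 (-0.83), Zfp207 (-0.74) and Tpp2 (-0.72), which did not pass either (limma adjusted p from 0.106 to 0.163 with the block).

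Of the gene lists, activity-regulated genes, the transcripts that neurons induce on depolarisation and calcium entry, were higher with β4a. Their median log2 change was 1.38, with 32 of 34 members above eGFP (camera adjusted p = 2.76e-14, adjusted p = 0.521 with an estimated correlation). Fosb stood at 7.34 ± 3.34 against 3.64 ± 0.81, Atf3 at 7.03 ± 1.57 against 5.23 ± 0.14 and Dusp6 at 9.92 ± 0.65 against 8.59 ± 0.19 (n = 3 each). The list median differed between replicates: 2.53 in replicate 1, 1.32 in replicate 2 and 0.04 in replicate 3. Npas4 differed by 10.75, 3.11 and -2.14 in these, but it stood at 3.02 in eGFP replicate 1, below the level of 4 used as the filter, so that the first of these is not exact. Without β4a replicate 1 the median was 0.92 and without β4a replicate 3 it was 2.17, with camera's call kept in each of the 12 fits that left out an array.

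Cholesterol synthesis genes were higher with β4a, with a median of 0.25 and 17 of 18 members above eGFP (camera adjusted p = 5.86e-09, adjusted p = 0.109 with an estimated correlation). The median stayed between 0.21 and 0.35 when arrays were left out. Fdft1, the squalene synthase gene, stood at 10.997 ± 0.086 against 10.47 ± 0.18, Msmo1 differed by 0.58, Idi1 by 0.56 and Cyp51 by 0.80. These 4 genes passed with limma when p was adjusted over the list alone (adjusted p = 0.0469), against 0 over all probe sets. Stress genes of the unfolded protein response were higher (median 0.23, 23 of 25 above; camera adjusted p = 1.59e-04, adjusted p = 0.585 with an estimated correlation). The chaperone Calr stood at 12.29 ± 0.04 against 12.05 ± 0.10. The median of this list was 0.08 without β4a replicate 1, 0.13 without eGFP replicate 3 and 0.35 without β4a replicate 3. Astrocyte markers were higher (median 0.33, 22 of 23 above; camera adjusted p = 4.72e-06, adjusted p = 0.585 with an estimated correlation). Slc1a3 stood at 10.25 ± 0.82 against 8.89 ± 1.13. The call ended without β4a replicate 3 (median 0.19, adjusted p = 0.246), and the median was 0.16 without eGFP replicate 2 and 0.61 without eGFP replicate 1. Presynaptic genes were lower (median -0.08, 22 of 31 below; camera adjusted p = 0.0131, adjusted p = 0.484 with an estimated correlation). This call ended in 4 of the 12 fits, those without eGFP replicate 2 (median -0.01, adjusted p = 0.462), eGFP replicate 3 (-0.04, 0.211), β4a replicate 1 (-0.09, 0.0799) or β4a replicate 3 (-0.10, 0.0701). Its median was -0.14 without eGFP replicate 1.

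With the replicate block 7 lists passed by camera for β4a, adding calcium channel subunits (median -0.22, 10 of 14 below, adjusted p = 0.00897, adjusted p = 0.238 with an estimated correlation) and granule cell identity genes (median -0.11, 19 of 27 below, adjusted p = 0.0157, adjusted p = 0.613 with an estimated correlation). Leaving out 1 array, in fits without the block, moved these 2 medians from -0.220 to 0.0524 and from -0.117 to 0.0168. Adjusted over the list alone with the block, 27 members of the lists passed by limma for β4a, against 0 over all probe sets for these list members. They included 11 activity-regulated genes, 6 cholesterol genes, Acsl6 (0.52), Kcna2 (-0.64), Robo1 (0.73), the proapoptotic Pmaip1 (0.73) and Hrk (-0.41), Nlgn3 (-0.42), Syn3 (-1.11) and Vamp1 (0.70).

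The β4b cultures were compared with eGFP in the same way. Zeb2, a zinc finger transcription factor of neural crest and glial cells, stood at 6.19 ± 0.13 with β4b and 4.82 ± 0.29 with eGFP (n = 3 each). It was 2.60-fold higher, with differences of 1.42, 1.55 and 1.17 in replicates 1 to 3. Limd2, a LIM domain protein, stood at 7.76 ± 1.29 against 6.34 ± 1.12 by its brighter probe set, 2.67-fold higher (1.67, 1.39 and 1.21). A dim second probe set of Limd2 differed by only 0.11. Insm1 stood at 7.88 ± 1.91 against 9.19 ± 1.64, 2.47-fold lower (-0.96, -1.48 and -1.48). With limma and Benjamini-Hochberg adjustment 0 probe sets passed without the block (607 at an unadjusted p under 0.05, 500 higher and 107 lower; 0 by a test of each probe set alone), and 3 passed with it, among 4447 at an unadjusted p under 0.05. These were Limd2 (limma adjusted p = 0.0295 with the block, 0.9999 without), Insm1 (0.0295 and 0.9999) and Zeb2 (0.0304 and 0.761).

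Leaving out 1 array in turn with the block gave from 0 to 61 probe sets for β4b. The count was 61 without eGFP replicate 1, 6 without β4e replicate 2, 3 without β4a replicate 1, 1 without β4a replicate 3 and 0 without any other. The log2 change stayed between 1.29 and 1.49 for Zeb2 (limma adjusted p 0.0149 to 0.181, passing in 4 of 12), between 1.26 and 1.53 for Limd2 (0.0467 to 0.150, passing in 3 of 12) and between -1.49 and -1.22 for Insm1 (0.00303 to 0.151, passing in 3 of 12). All 3 genes passed without eGFP replicate 1, β4a replicate 1 or β4e replicate 2, and Zeb2 also without β4a replicate 3. Without the block, leaving out 1 array moved Limd2 from 0.78 to 2.17, Insm1 from -2.31 to -0.40 and Zeb2 from 1.29 to 1.55. Other Zeb2 probe sets differed by 0.79 and 0.83, and a dim second probe set of Limd2 by 0.11.

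Further genes for β4b did not pass. Rrm2b, a p53-inducible ribonucleotide reductase subunit, stood at 4.29 ± 0.20 against 3.13 ± 0.05, 2610507B11Rik at 6.94 ± 0.15 against 6.08 ± 0.16 and Haghl at 8.23 ± 0.04 against 7.47 ± 0.18 (limma adjusted p = 0.761 each, 0.0520 with the block). Dpp10, an auxiliary subunit of A-type potassium channels, stood at 5.22 ± 0.27 against 3.98 ± 0.47, and Leprot differed by 0.97. Kcna2 stood at 10.00 ± 0.32 against 10.87 ± 0.14 and Zfyve28 at 9.99 ± 0.10 against 10.58 ± 0.15. Mapkbp1, Kmt2d, C330022C24Rik and Abl2 differed by -0.54, -0.53, -0.53 and -0.42. By the blocked p, A830010M20Rik (1.28), Rp2 (1.09), Prkcb (-1.27), Mtrex (-0.91), Zfp207 (-0.71) and Tpp2 (-0.68) were next (limma adjusted p = 0.0520 with the block for each).

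Of the lists, astrocyte markers were higher with β4b (median 0.50, 22 of 23 above; camera adjusted p = 6.83e-08, adjusted p = 0.633 with an estimated correlation). Slc1a3 stood at 10.41 ± 0.94 against 8.89 ± 1.13. The median was 0.28 without β4b replicate 3 and 0.77 without eGFP replicate 1. Presynaptic genes were lower (median -0.12, 25 of 31 below; camera adjusted p = 8.12e-04, adjusted p = 0.278 with an estimated correlation). Pclo stood at 10.91 ± 0.44 against 11.37 ± 0.33 and Syt1 at 12.96 ± 0.13 against 13.26 ± 0.05. The call ended without eGFP replicate 2 (median -0.07, adjusted p = 0.0707), and the median was -0.07 without eGFP replicate 3. Calcium channel subunits were lower (median -0.21, 11 of 14 below; camera adjusted p = 0.0115, adjusted p = 0.633 with an estimated correlation). Cacna1e stood at 11.73 ± 0.34 against 12.10 ± 0.13 and Cacna1b at 9.79 ± 0.14 against 10.12 ± 0.15. Cacna1a, the main partner channel of β4, differed by -0.17. The calcium channel call ended without eGFP replicate 1 (median -0.14, adjusted p = 0.155), eGFP replicate 3 (-0.15, 0.0963) or β4b replicate 2 (-0.09, 0.291).

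Activity-regulated genes were higher with β4b as well (median 0.73, 30 of 34 above; camera adjusted p = 0.00665, adjusted p = 0.917 with an estimated correlation). The replicate medians were 1.66, 0.58 and -0.07. The call ended without eGFP replicate 1 (median 0.41, adjusted p = 0.460) or β4b replicate 2 (median 0.66, adjusted p = 0.333), and the median was 0.41 without β4b replicate 1 and 1.17 without β4b replicate 3. Unfolded protein response genes were higher (median 0.23, 21 of 25 above; camera adjusted p = 0.0115, adjusted p = 0.917 with an estimated correlation). Leaving out eGFP replicate 1 (median 0.22, adjusted p = 0.147), eGFP replicate 3 (0.12, 0.0963) or β4b replicate 2 (0.19, 0.297) ended this call, and the median was 0.11 without β4b replicate 1. Cholesterol synthesis genes were higher (median 0.18, 15 of 18 above; camera adjusted p = 0.0115, adjusted p = 0.633 with an estimated correlation). Camera no longer called it without eGFP replicate 1 (median 0.21, adjusted p = 0.155), eGFP replicate 2 (0.13, 0.0705) or β4b replicate 3 (0.19, 0.467), nor in the blocked fit (adjusted p = 0.0844).

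With the block 8 lists passed for β4b by camera, adding granule cell identity (median -0.08, adjusted p = 0.00843, adjusted p = 0.651 with an estimated correlation), glutamate receptors (median -0.10, 17 of 26 below, adjusted p = 0.00843, adjusted p = 0.638 with an estimated correlation) and oligodendrocyte markers (median 0.18, 17 of 19 above, adjusted p = 0.0167, adjusted p = 0.651 with an estimated correlation). Each of these medians crossed 0 when 1 array was left out without the block (-0.142 to 0.0182, -0.34 to 0.18 and -0.0052 to 0.51 in turn). Adjusted over the list alone with the block, 32 members passed by limma. Among them were Pclo (-0.47), Syn3 (-1.32), Stx1a (-1.23) and Vamp1 (0.97) of the presynaptic list, Cacna1b (-0.33), Cacna1c (-0.39), Cacna1d (-0.85), Cacna1e (-0.37), Cacna1g (-0.33) and Cacng5 (1.15) of the calcium channels, Fat2 (-0.57), Reln (-0.39) and Mef2c (0.66) of the granule cell list, and Dusp6 (1.18), Acsl6 (0.63) and Kcna2 (-0.73, on its brightest probe set). Without the block 0 passed.

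At an unadjusted p under 0.05, the β4e cultures had the fewest probe sets against eGFP of the 3 variants. By limma and Benjamini-Hochberg, 0 probe sets passed for β4e with or without the block, with 83 at an unadjusted p under 0.05 without it (68 higher, 15 lower, and 0 by a test of each probe set alone) and 1277 with it (smallest adjusted p 0.873). Without the block the counts of all 3 variants lay below a share of 0.05 of the 23044 probe sets. With the block the count of β4e lay close to that share. Dpp10 stood at 4.92 ± 0.20 with β4e against 3.98 ± 0.47 (n = 3 each), Haghl at 7.95 ± 0.08 against 7.47 ± 0.18, Entpd5 at 5.81 ± 0.04 against 5.38 ± 0.04 and Cdv3 at 3.85 ± 0.08 against 4.25 ± 0.04. Of the other genes with the smallest p, Maneal, Nfatc1 and Ahcyl1 differed by 0.43, 0.35 and 0.33, and Sfxn2, Dlgap4, Zfyve28, Abl2 and 9530057J20Rik by -0.52, -0.39, -0.34, -0.32 and -0.30 (limma adjusted p = 0.9999 each). By the blocked p, the others were Limd2 (0.88), Kcnip2 (0.71), Rasgef1a (0.66), Acsl6 (0.49), Btbd9 (0.42), Insm1 (-0.75), Eif2s2 (-0.73), B3galnt2 (-0.49), Zfp207 (-0.47), Cemip (-0.47) and Atp2a2 (-0.42), also not passing (limma adjusted p = 0.873 each with the block).

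Astrocyte markers were higher with β4e (median 0.36, 22 of 23 above; camera adjusted p = 4.06e-05, adjusted p = 0.986 with an estimated correlation). This call ended without eGFP replicate 2 (median 0.10, adjusted p = 0.193) or eGFP replicate 3 (median 0.29, adjusted p = 0.0718). The median was 0.57 without eGFP replicate 1. Interferon response genes were higher (median 0.15, 18 of 19 above; camera adjusted p = 8.98e-04, adjusted p = 0.986 with an estimated correlation). Xaf1 stood at 5.62 ± 0.37 against 5.00 ± 0.23. The interferon call ended without eGFP replicate 2 (median 0.07, adjusted p = 0.243), eGFP replicate 3 (0.12, 0.0718) or β4e replicate 1 (0.05, 0.231), and the median was 0.32 without eGFP replicate 1 and 0.24 without β4e replicate 3. Activity-regulated genes had replicate medians of -0.16, 0.18 and -0.02. With the block, 6 members passed by limma adjusted over the list alone (Acsl6, Xaf1, Pmaip1, Kcnab2, Kcnip2 and Vamp1, by 0.49, 0.61, 0.64, 0.41, 0.71 and 0.70), and without it 0.

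The mean of the 3 variants was set against eGFP to find changes that they share. Insm1 stood at 8.01 ± 1.70 over the variant arrays (n = 9) and 9.19 ± 1.64 in eGFP (n = 3), a log2 change of -1.18. Limd2 differed by 1.01, Rasgef1a by 0.81, Hook3 by 0.75 and Haghl, a hydroxyacylglutathione hydrolase-like gene, by 0.65, at 8.12 ± 0.14 against 7.47 ± 0.18. The other probe sets of these genes did not all agree. For β4a, β4b and β4e in turn, 2 others of Haghl differed by 0.73, 0.76 and 0.49 and by 0.56, 0.62 and 0.43, and a dim one by -0.01, -0.15 and 0.02. The brightest of Hook3 differed by 0.07, -0.14 and -0.11, and 2 more by 0.11, 0.04 and -0.17 and by 0.28, 0.38 and 0.05. The second of Insm1 differed by -0.98, -0.83 and -0.19 (0.64 for β4e in replicate 1), that of Rasgef1a by 0.88, 1.11 and 0.69 and the dim one of Limd2 by -0.00, 0.11 and 0.14. With the block these 5 genes passed by limma and Benjamini-Hochberg (adjusted p = 0.0217 for Insm1 and 0.0471 for the other 4), among 4036 at an unadjusted p under 0.05. Without the block 0 passed (467 at an unadjusted p under 0.05, 381 higher and 86 lower). With the block and 1 array left out in turn, from 0 to 3 passed (3 without β4e replicate 1, 1 without eGFP replicate 1, β4a replicate 1 or β4e replicate 2, and 0 without any other). The highest limma adjusted p was 0.210 for Insm1 and 0.306 for the other 4. Without the block, leaving out 1 array moved Insm1 from -2.00 to -0.35, Limd2 from 0.37 to 1.42, Rasgef1a from 0.47 to 1.35, Hook3 from 0.55 to 0.85 and Haghl from 0.55 to 0.72.

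**Figure D2:**
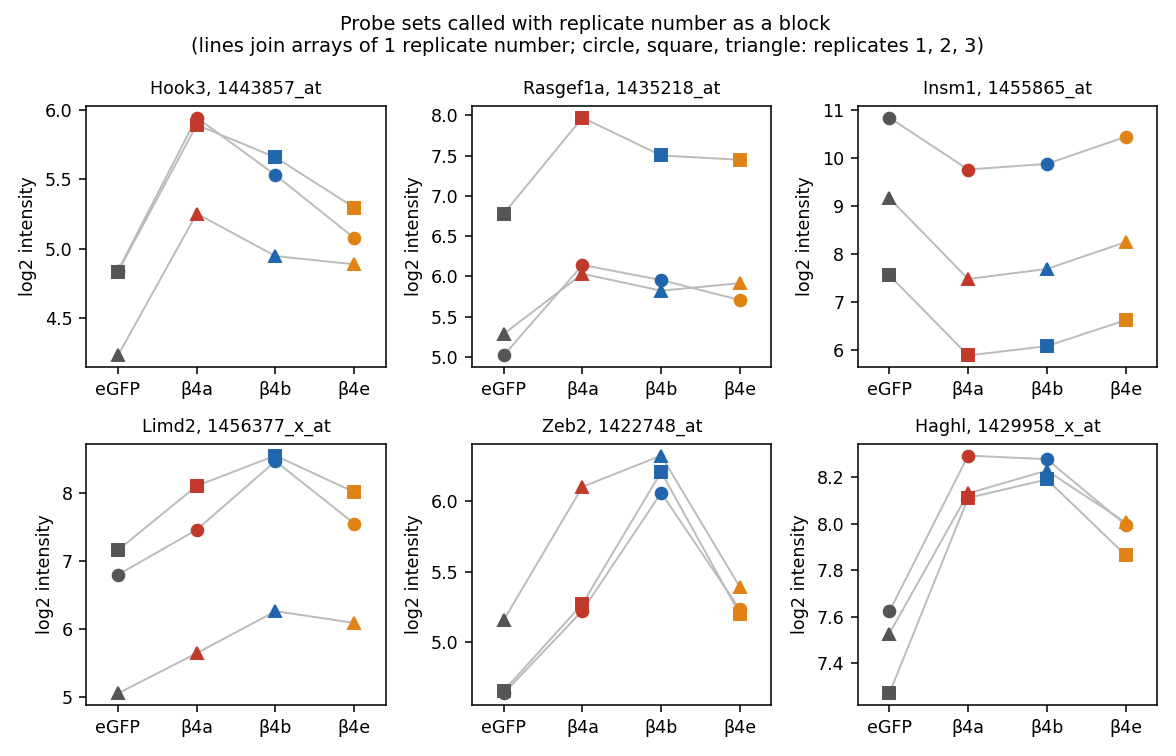
Log2 intensity on each of the 12 arrays of the genes that passed in the blocked fit, by group, with lines joining arrays of the same replicate number. Insm1 lies lower with β4a and β4b than with eGFP in each replicate number, and the other 5 genes lie higher.

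Genes just above the threshold for the mean of the variants with the block were A830010M20Rik (1.10), Robo1 (0.62), Mtrex (-0.72), Zfp207 (-0.64) and Tpp2 (-0.59), at a limma adjusted p of 0.0612, then Prkcb (-0.97, adjusted p = 0.0826) and Zfyve28 (-0.47, adjusted p = 0.0852). Adjusted over the list alone, 21 list members passed with the block by limma. Among them were Acsl6 (0.55), Pmaip1 (0.71), Kcnip2 (0.64), Vamp1 (0.79), Syn3 (-1.04), Grm5 (-0.88), Dlg2 (-0.51) and Cacna1d (-0.64).

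By camera 6 lists moved in the mean of the variants: astrocyte markers (median 0.40, adjusted p = 7.90e-08, adjusted p = 0.759 with an estimated correlation), activity-regulated genes (0.81; 1.03e-04; 0.915 with an estimated correlation), cholesterol synthesis (0.21; 1.03e-04; 0.316 with an estimated correlation), the unfolded protein response (0.21; 0.00113; 0.767 with an estimated correlation), presynaptic genes (-0.05; 0.00220; 0.316 with an estimated correlation) and calcium channels (-0.16; 0.0277; 0.759 with an estimated correlation). The activity-regulated call ended without eGFP replicate 1 (median 0.46, adjusted p = 0.379). The unfolded protein call ended without eGFP replicate 1 (0.20, 0.0738) or eGFP replicate 3 (0.11, 0.0678), and the presynaptic call without eGFP replicate 2 (-0.01, 0.374) or eGFP replicate 3 (-0.03, 0.0937). The presynaptic median was -0.11 without eGFP replicate 1 and -0.08 without β4e replicate 1. Calcium channels no longer passed without eGFP replicate 1 (-0.06, 0.306), eGFP replicate 3 (-0.09, 0.218), β4a replicate 2 (-0.07, 0.114), β4b replicate 2 (-0.10, 0.0890) or β4e replicate 2 (-0.09, 0.101). The median of astrocyte markers was 0.21 without eGFP replicate 2 and 0.65 without eGFP replicate 1, and that of cholesterol synthesis 0.12 without eGFP replicate 2. The block added granule cell identity (median -0.05, 18 of 27 below, adjusted p = 0.0103) and glutamate receptors (median -0.04, 17 of 26 below, adjusted p = 0.0226), against 0.0630 and 0.224 without it. Both medians crossed 0 when 1 array was left out without the block (-0.106 to 0.0271 and -0.26 to 0.13). With an estimated correlation and the block 0 lists passed. In no contrast did a list pass with an estimated correlation or by fry without the block, and with the block fry passed 1 list for β4a, 2 for β4b and 4 for the mean of the variants.

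The astrocyte marker difference varied with replicate number: it was -0.27, 0.40 and 0.80 in replicates 1 to 3 for β4a, -0.28, 0.66 and 1.02 for β4b, and -0.02, 0.72 and 0.29 for β4e. For a gene that astrocytes also express, this is not separated here from a change within neurons.

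**Figure D3:**
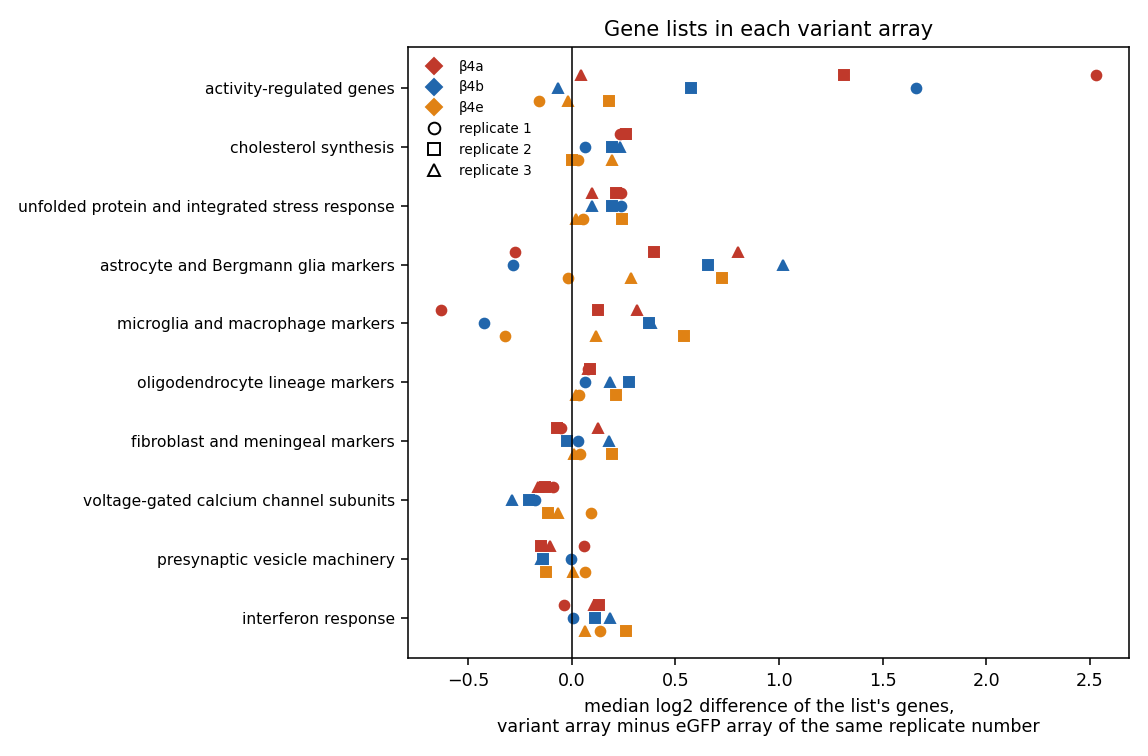
Median log2 difference from the eGFP array of the same replicate number for gene lists, by variant, with 1 point per replicate. Activity-regulated genes stand at 2.53 and 1.66 for β4a and β4b in replicate 1 and near 0 in replicate 3.

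The other lists did not pass in the mean of the variants by camera. Among neuronal lists, the median was -0.01 for potassium channels (adjusted p = 0.823), 0.01 for sodium and HCN channels (0.860), -0.01 for calcium handling (0.565), -0.04 for GABA receptors (0.714), 0.04 for axon cytoskeleton (0.900), 0.03 for granule progenitors and the Shh pathway (0.699), 0.11 for the cell cycle (0.588) and -0.15 for interneuron markers (0.699), and 0.00 for Purkinje cell markers (0.699). The reported β4 nuclear partners and targets had a median of 0.03, with 7 of 10 above (adjusted p = 0.900). Among stress and metabolic lists, the median was 0.11 for interferon response (0.0574), 0.16 for cytokines (0.699), 0.10 for heat shock (0.749), 0.11 for p53 and apoptosis (0.699), 0.14 for hypoxia and glycolysis (0.167), 0.12 for Wnt targets (0.823), 0.03 for ribosomal proteins (0.699) and 0.01 for oxidative phosphorylation (0.749). Oligodendrocyte, microglia and fibroblast markers had medians of 0.10 (0.699), 0.00 (0.823) and 0.07 (0.699). Camera's direction was down for β4 partners, Wnt targets, fibroblast markers and oxidative phosphorylation although their medians were above 0.

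The variants were then compared with each other. Rrm2b, by another of its probe sets than in the comparison with eGFP, stood at 4.87 ± 0.12 with β4b, 4.07 ± 0.19 with β4a and 3.74 ± 0.12 with β4e (n = 3 each). Its difference between β4b and β4e was 1.13, 1.005 and 1.27 in replicates 1 to 3 (limma adjusted p = 0.708, and 0.237 with the block). Dynlt3, a dynein light chain, stood at 9.22 ± 0.05 with β4b and 8.28 ± 0.13 with β4e, and Kcna2 at 10.00 ± 0.32 and 10.53 ± 0.04. By limma and Benjamini-Hochberg, 0 probe sets passed in any pair with or without the block: at an unadjusted p under 0.05 there were 56 for β4a against β4b, 153 for β4a against β4e and 175 for β4b against β4e (619, 1458 and 1638 with the block), and a test of each probe set alone gave 0 in each.

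For β4a against β4b, the smallest p values belonged to Pogz, Nab1, Pdilt, Galns and Mettl16 (0.66, 0.58, 0.36, 0.35 and 0.29) and to Rrm2b, Cxcl14, Gna13, Gpr61 and Cdc14a (-0.80, -0.67, -0.58, -0.50 and -0.41). For β4a against β4e they belonged to Atoh7, Nab1, Mcl1, Ncl and Cdv3 (1.52, 0.96, 0.77, 0.53 and 0.41) and to Ctu1, Cmtr1, Tmem161a, H13 and Wdr7 (-0.49, -0.47, -0.44, -0.41 and -0.36). For β4b against β4e the others were Leprot, 2610507B11Rik and Leprotl1 (0.81, 0.69 and 0.63) and Carmil3, Gtpbp2, Pdilt and Ap5z1 (-0.52, -0.49, -0.46 and -0.37). None of these passed.

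Activity-regulated genes differed between the variants in their medians: β4a stood above β4e by a median of 1.37 (33 of 34 above, camera adjusted p = 1.67e-24, adjusted p = 0.274 with an estimated correlation), above β4b by 0.60 (28 of 34, 1.34e-08, 0.971 with an estimated correlation), and β4b above β4e by 0.59 (31 of 34, 1.18e-06, 0.978 with an estimated correlation). Leaving out arrays moved the first of these from 0.87 (without β4a replicate 1) to 2.19 (without β4a replicate 3), with 0.91 without β4e replicate 1, and left its call. The β4a against β4b call ended without β4a replicate 1 (0.22, adjusted p = 0.106) or β4b replicate 3 (0.17, adjusted p = 0.148). It stood at 0.24 without β4a replicate 2 and 1.34 without β4a replicate 3. The β4b against β4e call ended without β4b replicate 2 (0.41, adjusted p = 0.0549) or β4e replicate 1 (0.42, 0.634), with 0.36 without β4b replicate 1, 1.05 without β4b replicate 3 and 1.02 without β4e replicate 2. In replicate 3 the list mean was 7.09 with β4a, 7.07 with β4b and 7.08 with β4e, so the order seen in replicates 1 and 2 was absent there. An exact test of the spread between the 4 groups, described in the closing section, gave p = 0.0729, so a ranking of the variants is not established.

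Cholesterol synthesis was higher with β4a than with β4e (median 0.23, 15 of 18 above; camera adjusted p = 3.37e-08, adjusted p = 0.141 with an estimated correlation, and a median of 0.13 without β4a replicate 1 and 0.11 without β4e replicate 2) and than with β4b (median 0.13, 15 of 18; 7.93e-05; 0.549 with an estimated correlation). The latter call ended without β4b replicate 1 (0.11, adjusted p = 0.0773) or β4b replicate 2 (0.10, 0.0831), and the median was 0.03 without β4a replicate 1 and 0.22 without β4b replicate 3. With β4b, presynaptic genes were lower than with β4e (median -0.09, 24 of 31 below; camera adjusted p = 0.00404, adjusted p = 0.524 with an estimated correlation). This call ended without β4b replicate 1 (-0.08, adjusted p = 0.317) or β4e replicate 3 (-0.08, 0.280). Astrocyte markers were higher with β4b than with β4e (median 0.20, 23 of 23 above; 0.00326; 0.978 with an estimated correlation). This call ended without β4b replicate 3 (0.01, adjusted p = 0.623) or β4e replicate 3 (0.14, 0.1002), and the median was 0.35 without β4b replicate 2 and 0.34 without β4e replicate 1. With the block 7 lists passed by camera for β4b against β4e, adding calcium channels (median -0.13, adjusted p = 0.00741, adjusted p = 0.376 with an estimated correlation), glutamate receptors (median -0.10, adjusted p = 0.0136, adjusted p = 0.730 with an estimated correlation), granule cell identity (median -0.03, adjusted p = 0.0468, adjusted p = 0.730 with an estimated correlation) and oligodendrocyte markers (median 0.15, adjusted p = 0.00607, adjusted p = 0.730 with an estimated correlation). The medians of these added lists all crossed 0 when 1 array was left out without the block (-0.25 to 0.13, -0.36 to 0.23, -0.121 to 0.0315 and -0.15 to 0.47 in turn).

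The F test asked for any difference among the 4 groups. By limma and Benjamini-Hochberg 0 probe sets passed, with 175 at an unadjusted p under 0.05 and 2705 with the block (smallest adjusted p 0.0727). The smallest p belonged to Rrm2b, 2610507B11Rik, Haghl, Dynlt3, Ahcyl1, Zeb2, Leprot, Kcna2, Dpp10 and Gna13, at a limma adjusted p of 0.999999 for each (0.150 to 0.276 with the block).

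Cacnb4 itself, the gene mutated in these mice and supplied by the virus, was read by 3 probe sets. The brightest stood at 12.09 ± 0.13 with eGFP, 12.03 ± 0.07 with β4a, 11.96 ± 0.15 with β4b and 11.98 ± 0.15 with β4e (n = 3 each). The second stood at 10.88 ± 0.46, 10.64 ± 0.30, 10.53 ± 0.20 and 10.73 ± 0.25, and the third at 9.74 ± 0.29, 10.02 ± 0.12, 10.18 ± 0.17 and 9.88 ± 0.42. The differences of the third from eGFP were 0.28, 0.44 and 0.14. None of the 3 probe sets passed in any contrast with eGFP by limma (lowest adjusted p 0.127, with the block). Where the probes lie relative to the construct and the mutation was not analysed here.

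**Figure D4:**
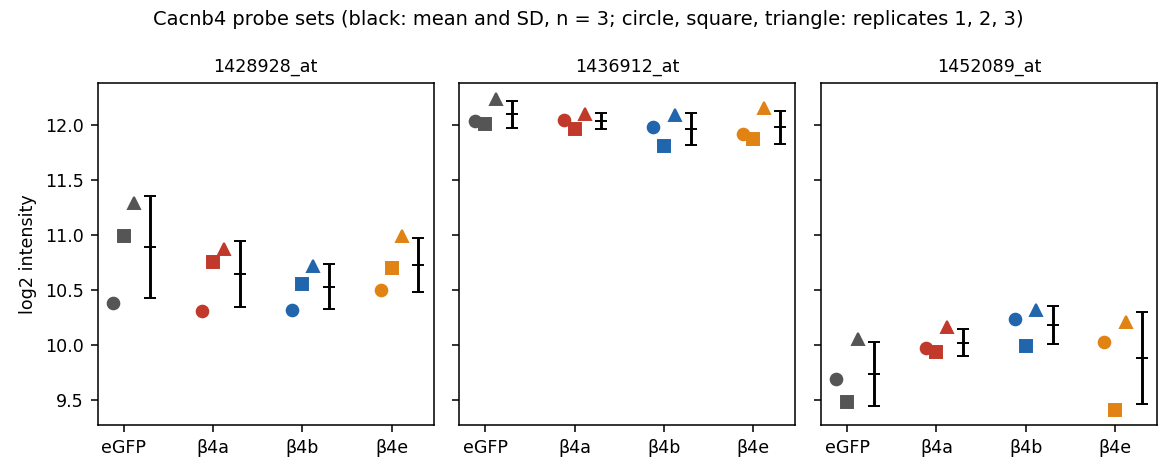
Log2 intensity of the 3 Cacnb4 probe sets on each array, by group, with the group means. The probe sets stand near 12, 11 and 10 in every group, with group means that differ by at most 0.44 from eGFP.

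The 3 comparisons with eGFP share their control arrays, which alone makes them alike. Across probe sets, which are not independent replicates, the log2 changes of β4a and β4b correlated with r = 0.847, β4a and β4e with 0.655 and β4b and β4e with 0.750, against 0.5003, 0.499 and 0.503 in simulations without an effect. The covariances were 0.0744, 0.0368 and 0.0437 against 0.0143, 0.0142 and 0.0144. This excess over the simulations was not separated here into effects of the variants and states of the shared eGFP arrays. Arrays of different replicate numbers share no array. Between these the median r was 0.330 for β4a with β4a (0.0705 to 0.349), 0.294 for β4b with β4b (0.218 to 0.517) and 0.0890 for β4e with β4e (-0.0411 to 0.187), from 3 values each. It was 0.295 for β4a with β4b (0.133 to 0.471), 0.139 for β4a with β4e (0.0235 to 0.387) and 0.176 for β4b with β4e (0.0726 to 0.467), from 6 values each. Most of these ranges overlap, so the medians do not establish a ranking.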

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

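In this part, the tests of a low eGFP array in replicate 1, of array states, of the astrocyte markers and of the construct's transcript were chosen only after the results were seen. The differences between variants that passed were, for activity-regulated genes, 1.37 between β4a and β4e, 0.60 between β4a and β4b and 0.59 between β4b and β4e, for cholesterol synthesis 0.23 between β4a and β4e and 0.13 between β4a and β4b, and between β4b and β4e -0.0943 for presynaptic genes and 0.20 for astrocyte markers. Each is a median log2 difference that passed by camera with the preset correlation, and 0 lists passed with an estimated one.

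Activity-regulated genes stood higher with β4a and β4b than with eGFP in replicates 1 and 2 and not in replicate 3. If the eGFP array of replicate 1 alone had been low, β4e should have stood above it by about as much, at least 1.27, but its median was -0.16 (-0.159, 95% bootstrap interval -0.310 to -5.08e-04), which argues against that. The interval resamples the genes of the list on 1 pair of arrays, so it leaves out the spread between cultures. Whether states of single arrays unrelated to the construct explain the pattern stays open: an exact test over the 576 reassignments of groups within replicate numbers gave a spread between groups as large in 42 of them (p = 0.0729). Signs of RNA handling differed in part along with the list. In replicate 1 the 3′ minus 5′ difference of Gapdh was 0.22 with β4a and 0.09 with β4b against 0.39 with eGFP and 0.40 with β4e, and in replicate 2 it was 0.08, 0.10, 0.12 and 0.05. The 18S probe sets rose with β4a and β4b by 0.31 and 1.72 in replicate 1 and by 0.76 and 0.42 in replicate 2. With β4e they differed by -0.74 and -0.10 in these, so in both replicates they parted β4a and β4b from β4e as the list did. In replicate 3 they rose by 0.69, 0.99 and 0.72 with β4a, β4b and β4e, where the list did not. RNA handling as an explanation was not tested and stays open. A response of calcium-dependent transcription to β4a and β4b, the explanation the design offers, may account for it and remains open as well.

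Astrocyte and Bergmann glia markers stood higher in the variant cultures, 22 of 23 in the mean of the variants and 6 of 9 variant arrays by their median. These 6 were the arrays of replicates 2 and 3, and arrays of 1 number share 1 eGFP array, so they are not 6 separate comparisons. States of the shared eGFP arrays were not separated here from effects of the variants. A lower share of granule cells would raise the markers of other cell types alike. Astrocyte markers exceeded microglia markers by 0.402 over all arrays (95% bootstrap interval 0.228 to 0.554), although the 2 medians had the same sign in each variant array. Microglia medians were -0.63, -0.42 and -0.32 for β4a, β4b and β4e in replicate 1 and between 0.12 and 0.54 in replicates 2 and 3. In these 2 replicates microglia markers rose by 0.293, and astrocyte markers exceeded them by 0.370 (0.122 to 0.658), oligodendrocyte markers by 0.561 (0.251 to 0.806) and fibroblast markers by 0.572 (0.309 to 0.843). The intervals resample the genes of a list and not the arrays, so they leave out the spread between cultures. The astrocyte median also lay above the microglia median in each variant array, though arrays of 1 number share their eGFP array. This excess of astrocyte markers argues against a lower share of granule cells as the whole cause and leaves a smaller part of it open. More astrocytes in the variant cultures is argued against in replicate 1 for β4a and β4b, where the medians were -0.274 and -0.282. For β4e in replicate 1 the median was -0.0186 (-0.109 to 0.0952), which does not decide it. More astrocytes stays open in replicates 2 and 3, where the lowest median was 0.285. A change of astrocyte expression at an equal number of cells may also explain it and was not tested.

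The third and the second of the Cacnb4 probe sets, by brightness, moved apart in the variant cultures, by 0.542 in the mean of 9 arrays. Ordinary disagreement between probe sets of a gene stays open, since 167 of 2074 other genes with 3 or more probe sets had a pair as far apart (a share of 0.0805), and 57 of 1211 with exactly 3 (4.71%). A transcript of the construct read by the rising probe set would put all 9 arrays above their eGFP array; 8 were, and the lowest stood at -0.0658, within the residual SD of 0.151, so this could not be decided either.

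Control probe sets outside the comparisons also differed from eGFP. The 18S ribosomal RNA probe sets stood higher by a mean of 0.589 with β4a (0.31, 0.76 and 0.69 in replicates 1 to 3) and by 1.04 with β4b (1.72, 0.42 and 0.99), and the poly-A spikes by 0.588 with β4b (1.29, 0.28 and 0.19) and 0.250 with β4e (0.59, 0.02 and 0.14), in both mostly through replicate 1. The hybridisation spikes differed by -0.56 with β4a (-0.80, -0.55 and -0.33) and -0.62 with β4b (-0.79, -1.05 and -0.03). With β4e the 18S probe sets differed by -0.04 (-0.74, -0.10 and 0.72) and the hybridisation spikes by -0.11 (-0.32, 0.22 and -0.23). No explanation of these was tested. Single arrays within a group of 3 were not tested for lying apart. The array weights that limma estimated over the 12 arrays without the block ran from 0.496 to 2.16, and the 4 arrays of replicate 1 had the lowest, up to 0.574. Such weights take in the differences between replicate numbers and do not measure array quality alone.

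Other splits of the arrays were counted for each result. For 3 against 3 arrays the splits are too few: without the block there are 10, and the real count was 0 probe sets in each of the 6 comparisons of groups, which all 10 reach by construction, with a highest other count of 0 in each but β4e against eGFP, where it was 5. With the block there are 4: for β4a and for β4b against eGFP the real count was 3 and the highest other 0 (1 of 4 splits), and in the other comparisons of groups both were 0 (4 of 4, again by construction). For lists, the real count and the highest other were 5 and 9 for β4a against eGFP (6 of 10 splits as large), 6 and 8 for β4b (6 of 10), 2 and 10 for β4e (9 of 10), 2 and 9 for β4a against β4b (9 of 10), 2 and 6 for β4a against β4e (10 of 10) and 3 and 10 for β4b against β4e (8 of 10).

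For the mean of the variants with the block, 5 probe sets were called and the highest of the other splits gave 4. Of 64 splits 1, the real one, was as large, which is the smallest share that 64 splits can give. This argues against chance for the full 12 arrays by a narrow margin and does not exclude it. With 1 array left out the real count was 0 to 3, below the 4 of that split, and other splits were not counted there. The count at an unadjusted p under 0.05 was 4036 against a highest other of 3392 (1 of 64). Chance was not excluded for the lists either (8 called, highest other 11, 9 of 64 as large). Without the block it was not excluded for lists (6 called, highest other 14, 48 of 100 drawn splits as large). For probe sets 0 were called, so that 100 of 100 drawn splits were as large by construction and the count decides nothing. The highest other split for probe sets gave 8513 calls, with replicate 1 of β4a, β4b and β4e as controls; of 5 drawn splits with any call, 4 had 3 control arrays of 1 replicate number, which points to the structure by replicate number. The count decides nothing for the F test either, where 0 were called without the block (highest other 2616, 100 of 100) and with it (highest other 0, 100 of 100).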

How the results depend on the processing

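In this part, the tests that combined the replicate block with a wider threshold, another prior, an estimated correlation, a left-out replicate number or a left-out array were chosen only after the results were seen. Over all alternatives 288 counts of probe sets stayed within 1.5 times the reported count and 28 did not, and for counts of lists 126 did and 56 did not. The reported count of probe sets was 0 in each comparison, so that staying within it means a count of 0. Of the list medians, 744 kept their direction and side of the threshold, 150 no longer passed, 48 passed in addition and 19 changed sign. Of the values of named genes 3918 kept their direction and side of the threshold, 89 passed in addition and 5 changed sign, and for Cacnb4 339 kept both and 3 changed sign. As none had passed without the block, keeping both says little about the size of a change.

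Without the block, no alternative called a probe set in any comparison. The block itself called 3 for β4a against eGFP, 3 for β4b and 5 for the mean of the variants, and changed no other count of probe sets. With the block and a threshold of 0.10 the counts were 3, 534 and 117, and 1 for the F test, as a wider threshold must give at least as many. With the block, trend and robust prior they were 1, 15 and 1, and 1 for the F test. With the block and without replicate 1 of every group they were 1, 3 and 1. With 1 array left out they ran from 0 to 2 for β4a, 0 to 61 for β4b, 0 to 1 for β4a against β4e, 0 to 3 for the mean of the variants and 0 to 1 for the F test. The blocked calls of Insm1, Hook3, Rasgef1a, Zeb2, Limd2 and Haghl were thus lost on leaving out most single arrays. Their log2 changes in those fits kept their sign. Calls also ended without an array outside the comparison, where the log2 change did not move. For β4a without β4b replicate 2, Hook3 stayed at 1.06 with a limma adjusted p of 0.117. A lost call thus need not mean that the array left out carried the change. What else ended the calls was not tested.

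For the lists, an estimated correlation gave 0 calls in all 7 contrasts, with or without the block. Fry gave 0 without the block, and with it 1 for β4a, 2 for β4b, 4 for the mean of the variants and 0 in the other 4 contrasts. Array weights gave 10 lists for β4a and 5 for β4a against β4e, no filter gave 4 for β4a against β4b, and the block gave 7 for β4b against β4e. With 1 array left out the counts ran from 4 to 9 for β4a, 2 to 7 for β4b, 0 to 8 for β4e, 1 to 6 for β4a against β4b, 2 to 8 for β4a against β4e, 2 to 8 for β4b against β4e and 3 to 9 for the mean of the variants. With the block and without replicate 1 of every group they were 11 for β4a, 7 for β4e, 5 for β4a against β4e and 11 for the mean. Without replicate 2 they were 0 for β4e, 6 for β4a against β4e and 11 for β4b against β4e, and without replicate 3 they were 4 for β4e and 4 for β4a against β4e. The cause was not tested.

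Medians that changed sign ran, with 1 array left out, for calcium channels from -0.220 to 0.0524 (β4a) and -0.25 to 0.13 (β4b against β4e), and for granule cell identity from -0.117 to 0.0168 (β4a), -0.142 to 0.0182 (β4b), -0.121 to 0.0315 (β4b against β4e) and -0.106 to 0.0271 (mean). Glutamate receptors ran from -0.34 to 0.18 (β4b), -0.36 to 0.23 (β4b against β4e) and -0.26 to 0.13 (mean), and oligodendrocyte markers from -0.0052 to 0.51 (β4b) and -0.15 to 0.47 (β4b against β4e). With the block, granule cell identity for β4b against β4e was 0.0030 without replicate 1 of every group, and without replicate 3 of every group glutamate receptors were 0.0454 in the mean and astrocyte markers -0.12 for β4b against β4e. Of genes, Tpp2 ran from -1.51 to 0.0597 (β4a) and -1.47 to 0.12 (β4b), Insm1 from -1.75 to 0.16 (β4e) and Zfp207 from -0.94 to 0.0762 (β4e). Cacnb4 ran from -0.41 to 0.0426 for the second probe set with β4e, -0.10 to 0.0116 for the brightest with β4a and -0.0221 to 0.37 for the third with β4e. These sign changes of genes and of Cacnb4 came from fits without the block, in which a left-out array leaves the replicate numbers unevenly spread over the groups. With the block and 1 array left out the sign was kept: Tpp2 stayed between -0.73 and -0.68 (β4a) and -0.74 and -0.62 (β4b), Insm1 between -0.93 and -0.66, Zfp207 between -0.54 and -0.38, and Cacnb4 between -0.28 and -0.07, -0.08 and -0.02, and 0.06 and 0.28 for the same 3 probe sets in turn. The imbalance thus accounts for these sign changes. List medians with 1 array left out were fitted only without the block. Within replicates 1 to 3, calcium channels for β4a kept 1 sign (-0.09, -0.13 and -0.17). So did granule cell identity for β4a (-0.10, -0.06 and -0.12) and β4b (-0.04, -0.06 and -0.10). Oligodendrocyte markers for β4b also did (0.06, 0.27 and 0.18), and glutamate receptors for β4b did not (-0.04, 0.09 and -0.22). For the lists that kept 1 sign, this points to the same imbalance. For the other list medians the cause was not tested.

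A trend in the prior was used for the list tests without the robust option. The signal over background and the number of arrays limit the precision of dim probe sets in particular.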

Other observations

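In this part, the tests between replicate numbers, fitted over all 12 arrays with limma, were chosen only after the structure of the arrays was seen. Transcripts used as markers of several cell types differed between replicate numbers, and whether cell composition, expression within cells or an array batch differed was not tested. Of interneuron genes, Gad2 stood at 9.24 ± 0.11 in replicate 1, 7.89 ± 0.23 in replicate 2 and 8.34 ± 0.22 in replicate 3 (n = 4 arrays each), and Slc32a1, the vesicular GABA transporter, at 9.54 ± 0.39, 6.83 ± 0.40 and 8.46 ± 0.20. Eomes, of unipolar brush cells, stood at 6.61 ± 1.27, 6.77 ± 0.49 and 5.89 ± 0.36 and did not pass (limma adjusted p = 0.780 for replicate 2 and 0.229 for replicate 3 against replicate 1). The myelin gene Mog stood at 8.93 ± 0.28, 7.57 ± 0.31 and 6.87 ± 0.28, and the chemokine Ccl2 at 8.30 ± 0.21, 6.76 ± 0.21 and 5.65 ± 0.45. Complement C1qa, a microglial gene, ran the other way, at 7.55 ± 0.10, 8.34 ± 0.36 and 9.14 ± 0.28, and Csf1r stood at 6.07 ± 0.21, 5.99 ± 0.21 and 7.05 ± 0.23. Insm1, which passed between groups in the blocked fit, stood at 10.24 ± 0.50, 6.54 ± 0.75 and 8.15 ± 0.75. The granule cell gene Neurod1 stood at 14.35, 14.34 and 14.29, near the top of the value range. Gabra6, another granule cell gene, stood at 13.92, 13.89 and 13.65. It passed as lower in replicate 3 than in replicate 1 (limma adjusted p = 0.0158) and did not pass in replicate 2 (0.731).

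Replicate 2 against replicate 1 gave 12256 probe sets past a Benjamini-Hochberg adjusted p of 0.05 (5576 higher, 6680 lower) and replicate 3 against replicate 1 gave 11115 (4555 higher, 6560 lower). By camera, oligodendrocyte markers were lower in replicate 2 (median -0.69; adjusted p = 0.00188; adjusted p = 0.443 with an estimated correlation) and in replicate 3 (-1.17; 7.25e-06; 0.450 with an estimated correlation) than in replicate 1. Microglia markers were higher in replicate 3 (0.47; 6.78e-05; 0.450 with an estimated correlation), glutamate receptors lower in replicate 2 (-0.82; 0.00186; 0.443 with an estimated correlation), and oxidative phosphorylation genes higher in replicate 2 (0.16; 1.30e-07; 0.443 with an estimated correlation). Interneuron and unipolar brush cell markers passed as lower in replicate 2 (-1.85; 0.0476; 0.464 with an estimated correlation) and not in replicate 3 (-0.79; 0.0522; 0.450 with an estimated correlation). Microglia markers did not pass in replicate 2 (median -0.05, camera adjusted p = 0.564), nor glutamate receptors in replicate 3 (-0.38, 0.130). Oxidative phosphorylation genes passed as higher in replicate 3 as well (0.02, 0.00203). Further lists passed by camera and are not printed here. Culture dates or batches were not given in the sources used here.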
